A study of Mus musculus with 2 samples.

How the data were processed

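H3K4me3 ChIP-seq was done on midbrain of mouse embryos at embryonic day 15.5, in 2 biological replicates that the labels describe as separate pools of 78 and 62 embryos of both sexes. Both samples form 1 group, so there was no comparison between groups, and the analysis describes where the mark lies and how far the replicates' peak lists overlap. Peaks and genes are not replicates, so p-values compare peaks or genes within this tissue, and n = 2 wherever replicates are compared.

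The authors deposited 4 peak lists on mouse build mm10 (GRCm38), in the narrowPeak format. Per the text files deposited with each sample, each replicate's list was made from that replicate's filtered alignments and 1 further file of unstated role, the pooled list from both replicates, and the replicated list from the pooled list and both replicates' lists. The aligner, the peak caller and their versions are not given in the sources used here. The signal value of each peak is the value that the authors deposited, and what it is relative to is not stated. The lists' −log10 q-value column is likewise the authors' own, and the deposited lists include weak peaks: from 4.96% (replicated) to 24.1% (replicate 1) of peaks had a −log10 q under 5. Peak values were used to describe, rank and filter peaks and to compare medians between classes of peaks within a list, and the replicates' signals at shared peaks were correlated between their lists. The design fixed in advance called the signal value a fold, and the same tests were used for it. The lists carry no read counts, so depth is unknown and no interval covers it. A deeper library can give more and wider peaks, so counts and widths are values of these lists.

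Peaks on the 19 autosomes, X and Y were used, with overlapping calls merged. The replicated list had 11 more peaks on scaffolds. Transcription start sites (TSSs) and genes were taken from GENCODE release M21, and the genome sequence from the same assembly. RefSeq transcripts and transfer RNA genes of that assembly were used for distal peaks. A protein-coding gene was marked when a replicated peak lay within 1 kb of any of its TSSs, and its signal was the highest of such a peak. Domains were replicated peaks joined over gaps of up to 1000 bp, a gene's domain was the widest at its TSSs, and the widest 5% of TSS domains were called broad. A peak of 1 replicate was shared when at least 50% of its length was covered by the other replicate's peaks. Peaks over 5 kb from every TSS were called distal. Exact (Clopper-Pearson) 95% binomial intervals were given for shares.

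Overlaps and the share at TSSs were tested against 1000 random placements on the same chromosomes with lengths kept (one-sided permutation test). Differences of medians were tested with 100000 permutations (two-sided). Gene lists were tested against all other protein-coding genes (marking) or all other marked genes (broad domains) with a two-sided Fisher's exact test and Benjamini-Hochberg adjustment over the lists, with a threshold of 0.05. CpG classes had their borders at observed/expected ratios of 0.48 and 0.75 in the 1 kb around the 5'-most TSS. The tests, thresholds, alternatives and the 45 gene lists were fixed before the data were examined, except where stated. Of the lists, 12 were defined by symbol pattern, and of the symbols in the others 574 matched a protein-coding gene and 6 did not. The lists overlap: patterning factors occur in several, and the other-region lists share genes with the midbrain lists.

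The lists cover midbrain and hindbrain patterning, midbrain dopaminergic, GABAergic, and glutamatergic and motor genes, serotonergic hindbrain, hindbrain and cerebellum, cortex, ventral forebrain and hypothalamus, and posterior Hox genes. They also cover neural progenitor, pan-neuronal, astrocyte, oligodendrocyte, microglia, endothelial, mural and meningeal, and erythroid cells. Those of other tissues and functions are liver, skeletal muscle, heart, epidermis, pluripotency, germline, housekeeping, receptor, axon guidance, Wnt, Shh and Notch, H3K4 methylation, polycomb, imprinted, sex-linked and immediate early genes. The symbol patterns took ribosomal, mitochondrial ribosomal, proteasome, histone, Hox, patterning factor, protocadherin, olfactory receptor, vomeronasal receptor, keratin-associated, defensin and numbered Zfp genes. The patterning factor pattern did not match Lmx1a, Lmx1b, Phox2a and Phox2b, so these were neither counted nor left out as patterning factors.

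Genes were named by a rule: the 20 protein-coding genes with the widest TSS domain, the 10 with the highest signal at a TSS, up to 4 marked members with the highest signal and up to 4 unmarked members in list order from each list discussed, and any member of the 4 midbrain lists. A gene or peak outside it was chosen after its values were seen.

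Alternatives were other overlaps, TSS windows of 500 bp and 2 kb, −log10 q of at least 5 or 20, gaps of 0 and 3000 bp, broad domains from 4 kb, distal distances of 2 and 10 kb, and either replicate's own list in place of the replicated list. Settings added after the data were seen were TSSs of basic protein-coding transcripts only, genes with a CpG ratio of at least 0.48 only, shared peaks left out, and patterning factors left out of other lists. Tests were tried on simulated data: for lists of 20 genes, 84% of those with a marking chance of 30% and 95% of those with 98% were called, against 1.5% of unchanged lists. The simulated lists shared no genes and their genes were marked independently, unlike the real lists, and the test of broad domains was not simulated. The median test gave p under 0.05 in 4% of simulations without a difference and 100% with a difference of 1 SD. These used 140 normally distributed values, far fewer than the peaks compared. Overlap counts matched bedtools with a difference of 0 over 5 quantities. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, matplotlib 3.10.9, bedtools 2.31.1 and samtools 1.23.1 were used.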

Results

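Trimethylation of lysine 4 of histone H3 (H3K4me3), a chromatin mark found at many promoters, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse midbrain at embryonic day 15.5. The samples formed 1 group of 2 biological replicates, which were separate pools of midbrains from 78 embryos (replicate 1) and 62 embryos (replicate 2) of both sexes. The authors' peak lists held 27580 peaks for replicate 1, 27561 for replicate 2, 29477 for both together (the pooled list) and 23417 in the list named replicated. These covered 36.9, 39.0, 42.1 and 40.5 Mb of the mm10 genome, with median peak widths of 1053, 1112, 1049 and 1520 bp. The sequencing depth is unknown because the lists carry no read counts. A gene was called marked when a replicated peak lay within 1 kb of any of its transcription start sites (TSSs), and its signal is the highest signal value that the authors gave such a peak on the pooled data.

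Some genes of the developing midbrain had wide H3K4me3 domains of similar width in both replicates. At Otx2, a homeobox gene required for midbrain identity, the TSS domain measured 18453 ± 1509 bp (mean ± SD, n = 2), where a domain is a run of peaks joined over gaps of up to 1000 bp. Domains measured 20884 ± 466 bp at Gata3 and 17123 ± 19.8 bp at Lhx5, transcription factor genes of midbrain GABAergic neurons. At En1, which patterns the midbrain and the anterior hindbrain, the domain measured 13979 ± 409 bp. Other genes differed more between the replicates: the Lhx2 domain spanned 9663 bp in replicate 1 and 21707 bp in replicate 2, and the Foxa1 domain 6128 and 1854 bp.

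Across the genome, 23872 of 27566 replicate 1 peaks (86.6%) were covered over at least 50% of their length by replicate 2 peaks, against a mean of 1.48% for peaks placed at random on the same chromosomes. In the other direction the share was 22410 of 27547 (81.4%), against 1.38% at random. Both shares passed a one-sided permutation test with 1000 random placements (p = 0.001, the smallest these can give). Signal values ranked the 23872 shared peaks alike in both lists, with Spearman's rho = 0.792 and Pearson's r of log2 values = 0.83. These are correlations across peaks, which are not independent replicates. Only 1 peak had identical coordinates in both lists. Peaks with no overlap in the other replicate numbered 2782 in replicate 1 (10.1%) and 3994 in replicate 2 (14.5%). Their median signal was 2.91 in replicate 1, against 20.3 for that list's shared peaks, and 2.98 against 24.2 in replicate 2. Both differences of medians passed a two-sided permutation test (p = 1e-05, the smallest that 100000 permutations can give). Among these peaks 26.8% (replicate 1) and 26.2% (replicate 2) lay within 1 kb of a TSS, compared with 68.5% and 70.2% of the shared peaks. Restricting both lists to peaks with −log10 q of at least 5 reduced the shares found in 1 replicate only to 3.82% and 7.63%.

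The replicated list was a subset of the pooled list: all 23406 of its peaks on the main chromosomes had the position and values of a pooled peak. Of 29460 pooled peaks, 22260 overlapped peaks of both replicates by at least 50% of either peak, and all 22260 were listed as replicated. A further 1146 replicated peaks did not meet that rule in both replicates, 1090 meeting it in 1 and 56 in neither. The 6054 pooled peaks left out had a median signal of 2.48, with a maximum of 4.72, against a median of 26.7 for those kept.

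The highest signal of a TSS peak, 77.2, was at Kdm5b (chromosome 1, 134559601 to 134562968, mm10), which encodes an H3K4 demethylase. Atp13a1 and Zfp866 shared the next peak at a common promoter, with a signal of 76.4. The signal reached 74.9 at Ssb, which encodes the La RNA-binding protein, 74.9 at the splicing regulator gene Tra2a and 74.4 at Mrpl3, a mitochondrial ribosomal protein gene. Kdm5a, which encodes another H3K4 demethylase, and Ccdc77 shared a peak with a signal of 74.1. Ppp3r1, a calcineurin subunit gene, had a signal of 74.0 and Oser1 one of 73.9, where the peak lay downstream of the 5'-most TSS.

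In all, 16342 of 23406 replicated peaks (69.8%, exact 95% interval 69.2 to 70.4%) lay within 1 kb of a TSS, against a mean of 10.5% for random placement (one-sided permutation p = 0.001, the smallest that 1000 placements can give). Of the other replicated peaks, 1170 (5%) overlapped exons, 2633 (11.2%) lay in introns and 3261 (13.9%) were intergenic. These had median signals of 5.81, 4.18 and 5.82, against 40 at TSSs. Protein-coding genes were marked in 14429 of 21938 cases (65.8%, exact 95% interval 65.1 to 66.4%). For 2746 of the marked genes (19%) the peak also lay within 1 kb of another protein-coding gene's TSS, so it could not be assigned to 1 gene. The marked share followed the CpG content of the 1 kb around the 5'-most TSS. It was 99.5% of 6040 genes with a CpG observed/expected ratio of at least 0.75, 95.5% of 6005 genes from 0.48 to 0.75, and 27.1% of 9893 genes under 0.48. In Fisher's exact test of the high against the low class, p was too small for the calculation to return.

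All 18 genes of the midbrain and hindbrain patterning list were marked (exact 95% interval 81.5 to 100%, Benjamini-Hochberg (BH) adjusted Fisher p = 0.00149). They included Spry1, a feedback inhibitor of FGF signalling, with a signal of 46.8, En2 with 32.8, En1 with 27.3 and Meis2 with 27.1. Signals were lowest at Wnt1 (4.44) and Fgf17 (4.30), which encode secreted signals of the midbrain-hindbrain boundary. All 16 midbrain GABAergic genes were marked (BH-adjusted Fisher p = 0.00391), among them Ascl1, a proneural factor gene (signal 44.2), Zfpm2 (40.2), Zfpm1 (34.8) and Lhx1 (34.4). Of the 16 midbrain glutamatergic and motor genes 15 were marked (BH-adjusted Fisher p = 0.0232), led by Pou4f1 (36.8), Ebf3 (36.0), Sox21 (28.5) and Sim1 (25.4). The exception was Phox2b, a regulator of cranial motor and autonomic neurons. The midbrain dopaminergic list had 17 of 20 genes marked, which did not pass (85.0%, BH-adjusted Fisher p = 0.124), although it did on replicate 2's own list (90.0%, 0.0415) and, in a setting chosen after the data were seen, with peaks shared with another gene's TSS left out (85.0% against 53.2% of other genes, 0.00976). Its marked genes included the dopaminergic regulator Nr4a2 (46.2), the GDNF receptor gene Ret (43.9), Calb1 (43.5), Pitx3 (37.7) and the dopamine transporter gene Slc6a3 (23.3). No replicated peak lay at Th and Ddc, which encode the enzymes of dopamine synthesis, or at the aldehyde dehydrogenase gene Aldh1a1. Replicate 2's own list had a TSS peak at Ddc, with a signal of 3.91, while Th and Aldh1a1 had none in either replicate's list. All 3 have CpG ratios in the low class: 0.212, 0.238 and 0.186.

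All 20 neural progenitor genes and all 20 pan-neuronal genes were marked (BH-adjusted Fisher p = 0.00115 for each). The strongest were the RNA-binding protein genes Msi1 (68.3) and Msi2 (66.2) among progenitor genes, and the adhesion molecule gene Ncam1 (71.3) and the microtubule protein gene Map2 (66.3) among neuronal genes. Of 14 astrocyte genes 11 were marked, including Nfia (54.7) and the glutamate transporter gene Slc1a2 (47.8), while Gfap, Aqp4 and S100b were unmarked. Of 14 oligodendrocyte genes 8 were marked, including the myelin genes Mbp (39.1) and Cnp (38.9), while the myelin genes Plp1, Mog, Mag and Mobp were unmarked. For Mbp the widest domain lay at the 5'-most TSS, and its other TSSs were not examined apart. Neither glial list passed against the other genes (BH-adjusted Fisher p = 0.481 and 0.631).

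Only 1 of 16 microglia and macrophage genes was marked (6.25%, BH-adjusted Fisher p = 5.59e-06). This was Hexb, a lysosomal enzyme gene with a signal of 32.3, while Aif1, Cx3cr1, P2ry12 and Csf1r were unmarked. Erythroid genes were marked in 5 of 15 cases (BH-adjusted Fisher p = 0.0185), including Klf1 (25.5) and Gypa (25.1), while Gata1, Alas2 and the globin genes Hbb-bt and Hbb-bs were unmarked. Endothelial genes were marked in 10 of 16 cases and genes of mural, meningeal and fibroblast cells in 11 of 16, and neither list passed (BH-adjusted Fisher p = 0.833 and 1). The vascular receptor gene Kdr had a signal of 44.9, and the pericyte channel gene Kcnj8 one of 24.9.

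Regulators of other brain regions were often marked too. All 16 cortex genes were (BH-adjusted Fisher p = 0.00391), led by Bcl11b (53.4), Bhlhe22 (47.1), Satb2 (41.7) and Lhx2 (32.9). Signals were low at Foxg1 (6.71), Tbr1 (4.93), Fezf2 (3.86) and Neurod6 (3.39), against a median of 44.9 for all marked genes. The Foxg1 peak also lay at the TSS of Gm43517, and Emx2, Six3 and Sp8 are in a midbrain list too. Of 16 genes of the ventral forebrain and hypothalamus 15 were marked (BH-adjusted Fisher p = 0.0232), with the peptide hormone precursor gene Pomc unmarked. Serotonergic hindbrain genes were marked in 8 of 10 cases and hindbrain and cerebellum genes in 12 of 18, and neither list passed (BH-adjusted Fisher p = 0.574 and 1). The serotonin transporter gene Slc6a4 was marked (34.1), and the serotonin synthesis gene Tph2 was not. Posterior Hox genes, which pattern the trunk and limbs, were marked in 6 of 17 cases (BH-adjusted Fisher p = 0.0244). The highest signals were 6.10 at Hoxd9 and 5.43 at Hoxd13, and Hoxa9, Hoxa10 and Hoxa11 were among the unmarked genes.

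Liver, germline, muscle and heart genes were marked less often than all other protein-coding genes, in tests that did not match genes on CpG content. Most liver, muscle, heart, microglia and erythroid genes had CpG ratios under 0.48, and 27.1% of all genes of that class were marked. Over whole lists, the muscle (31.25%), heart (35.7%) and erythroid (33.3%) shares were not below that, and the liver (11.1%) and microglia (6.25%) shares were. These whole-list shares include genes of higher CpG ratio, such as the marked genes Actn2 (0.516), Pax7 (0.628), Hand2 (0.745) and Tal1 (0.803). They therefore cannot be compared directly with the share of the low class. No list was tested within that class alone. Liver genes were marked in 2 of 18 cases (BH-adjusted Fisher p = 1.11e-05), Foxa3 (51.3) and the transferrin gene Trf (3.52), while Alb, Apoa1, Apoa2 and Apob were unmarked. Both peaks also lay at another gene's TSS, that of Sympk and that of Gm20425, so they cannot be assigned to the liver genes, and without such shared peaks 0% of the list was marked. Trf had no TSS peak in replicate 1's own list, so without replicate 2 the liver share was 5.56%. Germline genes were marked in 3 of 18 cases (BH-adjusted Fisher p = 9.13e-05): Gdf9 (40.4), whose peak was shared with Uqcrq, Dazl (27.4) and Tdrd1 (4.02). Skeletal muscle genes were marked in 5 of 16 (BH-adjusted Fisher p = 0.0101) and heart genes in 5 of 14 (BH-adjusted Fisher p = 0.0314), where the highest signals were 29.9 at Actn2 and 7.38 at Hand2. Epidermis genes (10 of 18) and pluripotency genes (8 of 16) did not pass (BH-adjusted Fisher p = 0.526 and 0.243), although pluripotency genes passed as lower with −log10 q of at least 20 (37.5%, 0.0481). The pluripotency genes Pou5f1 and Nanog were unmarked, and Klf4 was marked (36.9).

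Among functional groups, all 20 housekeeping genes (BH-adjusted Fisher p = 0.00115), all 25 axon guidance genes (0.000156), all 29 Wnt, Shh and Notch genes (4.40e-05), all 18 genes of the H3K4 methylation machinery and all 18 polycomb genes (0.00149 each) and all 16 immediate early genes (0.00391) were marked. The guidance cue gene Efna5 had a signal of 60.6, the receptor gene Robo1 58.7, Notch2 62.6, the polycomb methyltransferase gene Ezh2 60.3 and the actin gene Actg1 71.7. Glutamate and GABA receptor genes were marked in 25 of 26 cases (BH-adjusted Fisher p = 0.00131), all except Gabra6. Imprinted genes were marked in 16 of 17 cases (BH-adjusted Fisher p = 0.0161), all except Ndn. Dopamine and serotonin receptor genes (14 of 18) and sex-linked genes (7 of 9) did not pass (BH-adjusted Fisher p = 0.403 and 0.779), and Drd3, Htr2b, Htr3a and Htr3b were the unmarked receptor genes.

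Gene families set by symbol showed the widest range. All 77 mitochondrial ribosomal protein genes, 79 of 82 ribosomal protein genes and 37 of 39 proteasome genes were marked (BH-adjusted Fisher p = 1.04e-13, 1.75e-10 and 9.13e-05). The ribosomal exceptions were Rpl10l, Rpl39l and Rpl3l, and the proteasome exceptions were the testis subunit gene Psma8 and the thymus subunit gene Psmb11. Patterning transcription factor families had 106 of 112 genes marked (BH-adjusted Fisher p = 1.85e-12), numbered Zfp genes 322 of 365 (5.62e-22), histone cluster genes 59 of 67 (0.00015) and clustered protocadherins 48 of 57 (0.00495). Hox genes as a whole were marked in 16 of 39 cases (BH-adjusted Fisher p = 0.00379), with the highest signals at Hoxa7 (25.7) and Hoxd1 (23.7). Marking was nearly absent from olfactory receptor genes (3 of 1135, adjusted p too small for the calculation to return) and vomeronasal receptor genes (1 of 327, BH-adjusted Fisher p = 7.02e-151). It was also rare at keratin-associated protein genes (1 of 57, BH-adjusted Fisher p = 3.14e-24) and not found at 64 defensin genes (BH-adjusted Fisher p = 1.99e-29), which allows a share of up to 5.6%. The strongest of these exceptions were Vmn1r4 (54.8), whose peak also lay at the TSS of Nt5c3, and Olfr94 (47.0).

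**Figure D1:**
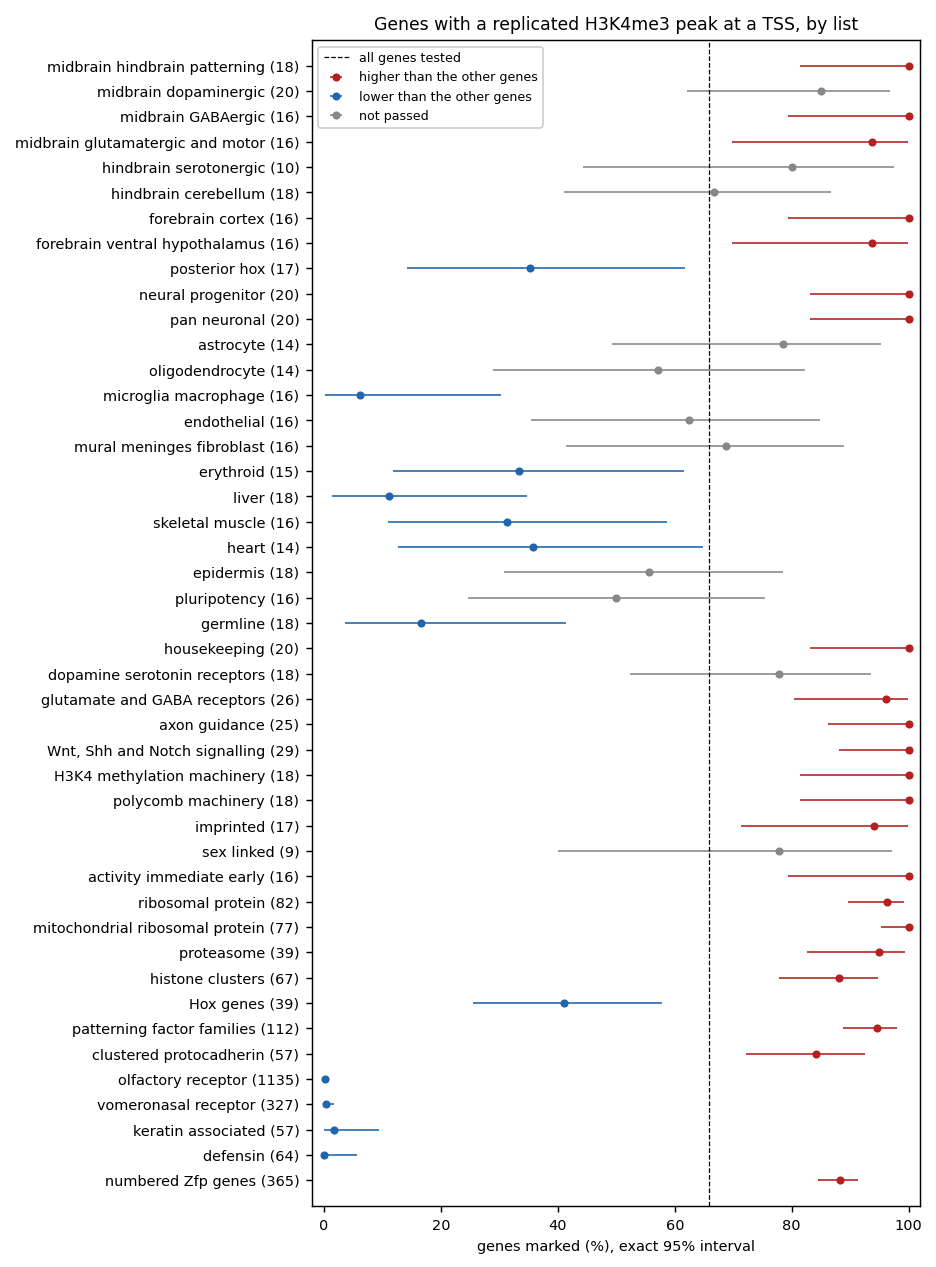
Share of genes with a replicated H3K4me3 peak within 1 kb of a TSS (horizontal axis, %) for each of the 45 gene lists (vertical axis, number of genes in brackets), with exact 95% intervals as bars. Red lists (22) were higher and blue lists (12) lower than all other protein-coding genes at a BH-adjusted Fisher p under 0.05, grey lists (11) did not pass, and the dashed line is the share of all protein-coding genes (65.8%).

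Altogether 22 of the 45 lists were marked more often than the other protein-coding genes, 12 less often and 11 did not pass, in tests that take genes as units within 1 tissue. Among genes with a CpG ratio of at least 0.48, a comparison chosen after the data were seen, 97.52% of the genes outside the patterning list were marked, so higher marking could hardly be tested there, and several lists kept only 1 gene. Lists lower there were histone clusters (90.8%), clustered protocadherins (85.7%), germline (33.3%), all Hox (45.5%), posterior Hox (31.3%) and hindbrain and cerebellum genes (80%, BH-adjusted Fisher p = 0.0392). With −log10 q of at least 20 the protocadherins turned to fewer than the other genes (31.6%, BH-adjusted Fisher p = 4.12e-06) and both forebrain calls ended, at 81.3% for cortex and 87.5% for ventral forebrain genes against 64.1% of other genes (BH-adjusted Fisher p = 0.233 and 0.0875). Without replicate 1 both Hox calls ended, at 56.4% for all Hox and 41.2% for posterior Hox genes against 66.1% (BH-adjusted Fisher p = 0.279 and 0.052). With a window of 2 kb the heart and posterior Hox calls ended, at 42.9 and 41.2% against 66.6% (BH-adjusted Fisher p = 0.113 and 0.0508). Leaving out peaks shared with another gene's TSS, also chosen after the data were seen, lowered the share of other genes to 53.3% and turned histone clusters to fewer (38.8%, BH-adjusted Fisher p = 0.0326). The calls for erythroid, heart and posterior Hox genes ended there with their own shares unchanged at 33.3, 35.7 and 35.3% (BH-adjusted Fisher p = 0.243, 0.345 and 0.201). Muscle (25%), imprinted (76.5%), mitochondrial ribosomal (58.4%), proteasome (69.2%) and all Hox genes (38.5%) also no longer passed (BH-adjusted Fisher p = 0.0666, 0.117, 0.489, 0.0828 and 0.108).

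The widest H3K4me3 domain of a protein-coding gene, at the nuclear receptor gene Nr2f2, spanned 25981 bp (24067 ± 1575 bp, mean ± SD over the 2 replicates' own lists), Meis2 22855 bp (23450.5 ± 1105 bp), the POU factor gene Pou3f3 21967 bp (21810 ± 133 bp) and Ebf3 19971 bp (22067.5 ± 238 bp). A domain of 20702 bp over Gata3 (chromosome 2, 9869636 to 9890337, mm10) also covered the TSSs of 4930412O13Rik and 9230102O04Rik. Lhx9, Otx2, Lhx5 and Lhx1 followed with 18585, 17498, 17144 and 17084 bp, and Nr2f1, Mn1, Pou3f2, Irx2, Six3 and Tfap2b had 14933 to 15542 bp. The domains of Zfhx3 (24164 bp) and Nfib (17326 bp) lay downstream of the 5'-most TSS. Zfhx3 had 13168 and 15426 bp in the replicates' own lists, and Lhx2 (21769 bp) was as wide in replicate 2 only, with 9663 bp in replicate 1.

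**Figure D2:**
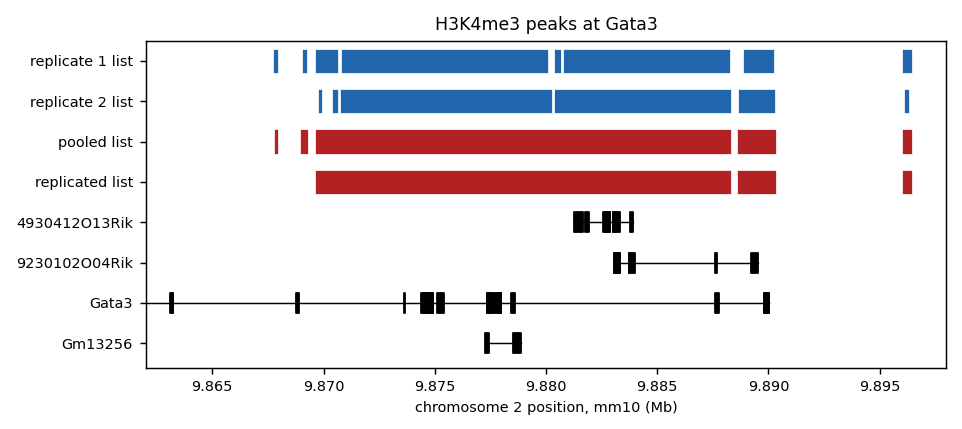
Peaks of the 4 lists (bars, blue for the replicates and red for the pooled and replicated lists) and GENCODE genes (lines, with exons as boxes) around the Gata3 domain on chromosome 2, 9869636 to 9890337 (mm10, horizontal axis in Mb). The replicate 1, replicate 2, pooled and replicated lists hold 8, 6, 5 and 3 peaks here, and the 20702 bp domain runs from the TSS of Gata3 into its gene body.

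Of 14242 TSS domains, with a median width of 2182 bp, the widest 5% (713 domains, 5100 bp or more) were called broad. They marked 814 of 14429 genes (5.64%), and 619 of the 814 (76.0%) had a domain that wide in each replicate's own list. The midbrain lists were far above this share. Broad domains lay at 12 of 16 GABAergic genes (75.0%, exact 95% interval 47.6 to 92.7%, BH-adjusted Fisher p = 3.12e-11), including the GABA synthesis genes Gad1 (11863 bp) and Gad2 (11139 bp) and the vesicular GABA transporter gene Slc32a1 (11932 bp). They lay at 11 of 15 glutamatergic and motor genes (73.3%, BH-adjusted Fisher p = 2.81e-10), including the vesicular glutamate transporter gene Slc17a6 (13930 bp), Barhl1 (11199 bp) and Tfap2d (10248 bp). The patterning list had 10 of 18 (55.6%, BH-adjusted Fisher p = 5.62e-08), with En1 (13837 bp), Pax7 (8335 bp) and En2 (7644 bp) broad and Fgf8 (1575 bp), Pax2 (2096 bp) and Wnt1 (3837 bp) not. The dopaminergic list had 7 of 17 (41.2%, BH-adjusted Fisher p = 0.000102), with Nr4a2 (8425 bp) and Ebf1 (6363 bp) broad and Pitx3 (2026 bp) and Slc6a3 (1083 bp) not. Over all 4 lists 38 of 64 marked genes were broad, and 33 of the 38 were that wide in each replicate's own list.

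**Figure D3:**
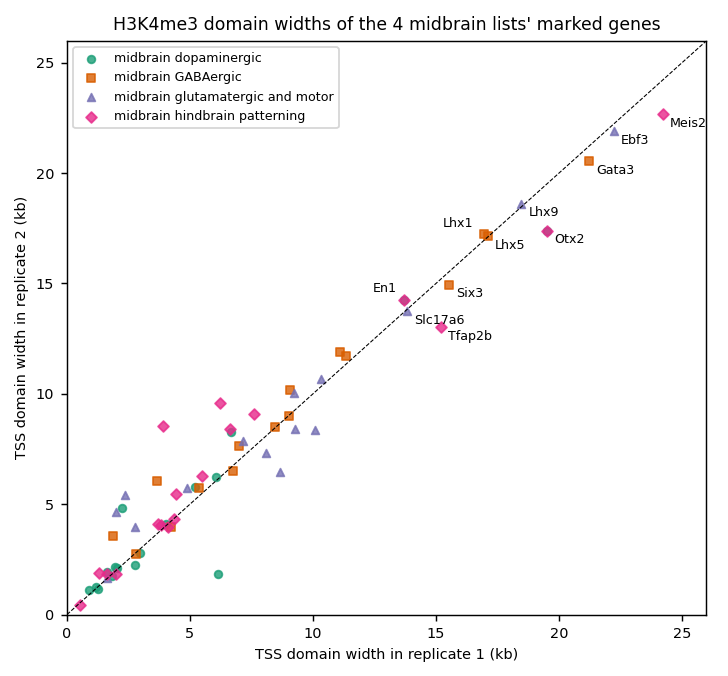
Width of the TSS domain (kb) in replicate 1 (horizontal axis) and replicate 2 (vertical axis) for each marked gene of the 4 midbrain lists, by list (colour and symbol), with the line of equal widths dashed. Names are given for the widest domains, from Slc17a6 (13820 and 13735 bp) to Meis2 (24232 and 22669 bp), and Foxa1, at 6128 and 1854 bp, lies far from the line.

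Neural progenitor and pan-neuronal genes had broad domains in 11 of 20 cases each (55.0%, BH-adjusted Fisher p = 1.33e-08), including Msi1 (9321 bp) and the splicing regulator gene Celf4 (11818 bp). So did 13 of 25 axon guidance genes (1.62e-09), among them Efna5 (11185 bp), and 12 of 29 Wnt, Shh and Notch genes (BH-adjusted Fisher p = 1.12e-07), among them the beta-catenin gene Ctnnb1 (8820 bp) and the Wnt receptor gene Fzd1 (7278 bp). Patterning transcription factor families had 51 of 106 (48.1%, BH-adjusted Fisher p = 6.23e-34). In lists of other brain regions the counts were 5 of 12 for hindbrain and cerebellum (BH-adjusted Fisher p = 0.00141, Zic1 13359 bp, where the strongest peak was shared with Zic4), 4 of 16 for cortex (0.0292, Bcl11b 10585 bp) and 4 of 15 for ventral forebrain and hypothalamus (0.0262, Dlx6 11649 bp). Broad domains were also more frequent at astrocyte genes (4 of 11, BH-adjusted Fisher p = 0.00884, Nfia 6412 bp), glutamate and GABA receptor genes (6 of 25, 0.00884, Grik2 9310 bp) and immediate early genes (4 of 16, 0.0292). The same held for polycomb genes (4 of 18, BH-adjusted Fisher p = 0.0422) and histone clusters (9 of 59, 0.0186, Hist3h2a 7872 bp).

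**Figure D4:**
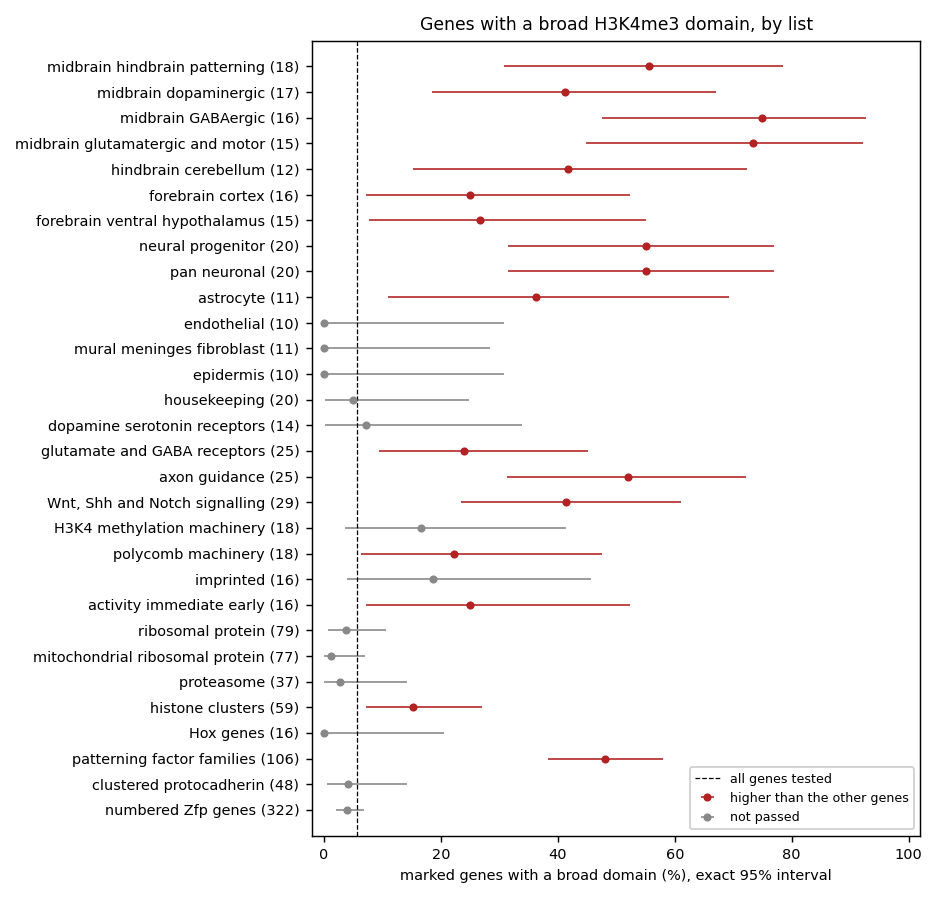
Share of marked genes with a broad domain (horizontal axis, %) for each list with at least 10 marked genes (vertical axis, number of marked genes in brackets), with exact 95% intervals as bars. Red lists were higher than the other marked genes at a BH-adjusted Fisher p under 0.05, grey lists did not pass, and the dashed line is the share of all marked genes (5.64%).

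Of 44 lists with a marked gene, 17 had more broad genes than the other marked genes, 0 had fewer and 27 did not pass. Housekeeping genes had 1 of 20 (Actg1, 6512 bp) and ribosomal protein genes 3 of 79, but both passed as higher in 1 other setting. Housekeeping genes were broad in 25% without replicate 1 (BH-adjusted Fisher p = 0.0125), and ribosomal protein genes in 16.5% with a gap of 3000 bp (BH-adjusted Fisher p = 0.0061). The counts were 1 of 77 for mitochondrial ribosomal protein genes, 1 of 37 for proteasome genes, 2 of 48 for protocadherins and 13 of 322 for numbered Zfp genes, which passed as lower from 4 kb (7.76% against 12.5%, BH-adjusted Fisher p = 0.0258). Hox genes had 0 of 16, posterior Hox genes 0 of 6, endothelial genes 0 of 10, mural, meningeal and fibroblast genes 0 of 11, epidermis genes 0 of 10 and pluripotency genes 0 of 8. Serotonergic hindbrain and oligodendrocyte genes had 2 of 8 each, H3K4 machinery genes 3 of 18, imprinted genes 3 of 16 and dopamine and serotonin receptor genes 1 of 14. Of these, serotonergic genes passed with a gap of 3000 bp and without replicate 1 (37.5% in each, BH-adjusted Fisher p = 0.0292 and 0.0202), imprinted genes with a gap of 3000 bp (25%, 0.0404) and with CpG ratios of at least 0.48 (30%, 0.0447), and H3K4 machinery genes with no gap (27.8%, 0.0133). The remaining lists that did not pass had at most 7 marked genes: erythroid and skeletal muscle genes had 1 of 5 broad each, and sex-linked, heart, germline, olfactory receptor, liver, microglia, vomeronasal and keratin-associated genes had 0. Lists share members, and with patterning factors left out of every other list, a setting chosen after the data were seen, the calls for patterning (25%), cerebellum (12.5%), cortex (10%), ventral forebrain (0%) and astrocyte genes (30%) ended (BH-adjusted Fisher p = 0.184, 0.743, 0.843, 1 and 0.0552). The patterning list still held Lmx1b there (5701 bp, broad), which the symbol pattern did not match. The polycomb share was unchanged there (4 of 18), and only its adjusted p moved over the threshold (BH-adjusted Fisher p = 0.0552). With no gap allowed between peaks the calls for astrocyte (27.3%), polycomb (16.7%), histone (6.78%) and ventral forebrain genes (0%) ended (BH-adjusted Fisher p = 0.0674, 0.218, 1 and 1), and 11 of the 20 widest domains shrank by over 1.5 times, such as Nr2f2 to 8686 bp. Among genes with a CpG ratio of at least 0.48 the call for glutamate and GABA receptor genes ended (18.8%, BH-adjusted Fisher p = 0.13).

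Width and height ranked TSS domains only partly alike, with Spearman's rho = 0.486 across 14242 domains, which are not independent replicates. Gata3 had a domain of 20702 bp with a signal of 19, and the homeobox gene Six3 15283 bp with 16.2. Kdm5b had 3368 bp with a signal of 77.2, and Mrpl3 1399 bp with 74.4.

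Peaks over 5 kb from every GENCODE TSS were weaker and narrower than those at TSSs. The strongest was on chromosome 12, 8640064 to 8641854 (mm10), with a signal of 66.4, 32.3 kb from the nearest GENCODE TSS, that of the RNA-binding protein gene Pum2. Next came a peak on chromosome 1, 171037663 to 171039235, with a signal of 59.7, within 1 kb of the transfer RNA genes n-TDgtc4, n-TGtcc2 and n-TLcag3 of the RefSeq annotation. Both peaks were chosen after their values were seen. In all 4082 of 23406 replicated peaks (17.4%, exact 95% interval 17.0 to 17.9%) lay over 5 kb from every GENCODE TSS. Their median signal was 5.40 against 40 for TSS peaks, and their median width 626 bp against 1980.5 bp (two-sided permutation p = 1e-05 for each, the smallest that 100000 permutations can give). The share was 25.3% beyond 2 kb and 12.3% beyond 10 kb.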

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

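No test was chosen after the result was seen for these peaks, which were only counted. The replicated list held 11 peaks on 6 unplaced or unlocalised scaffolds, which no comparison used. They are given because they lie outside the data compared, and no expected number was computed for them. Their median signal was 12.9 and their highest 39.5.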

How the results depend on the processing

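The added settings (basic transcripts, CpG ratio of at least 0.48, shared peaks left out, patterning factors left out) were chosen only after the results were seen. In the alternatives fixed in advance, 197 of 204 calls of lists for marking and 81 of 85 for broad domains held, and 28 of 34 and 13 of 17 lists held in all of them; causes of the changes below were not tested. The midbrain lists had 61 to 65 marked genes and 28 (gap of 0 bp) to 43 (from 4 kb) broad genes, against 64 and 38 as reported. Depth limits the weakest peaks and could not be varied.

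With 50% of both peaks required the rank correlation was 0.896, and at −log10 q of at least 5 it was 0.819, with 3.82% and 7.63% of peaks in 1 replicate only and 16.9% distal. Distal peaks were 25.3% beyond 2 kb and 12.3% beyond 10 kb. Genes marked were 66.6% with 2 kb, 64.2% at −log10 q of at least 20 and 64.5% with basic transcripts. Without 1 replicate, shares ranged from 63.8 to 64.3% at TSSs and 65.8 to 66.1% of genes marked, with 22 to 23 lists higher, 10 to 12 lower and 17 to 19 broad. Width against signal gave 0.576 with a gap of 0 bp and 0.439 with 3000 bp. With CpG ratios of at least 0.48, where 97.52% of genes outside the patterning list were marked and higher marking could hardly be tested, 0 lists were higher and 6 lower, and without patterning factors 11 were broad.

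In 45 cases a list's direction against the other genes turned, 28 of them with neither value past the threshold. For marking, hindbrain and cerebellum genes were at 61.1% (−log10 q of at least 5) and 50% (at least 20), where astrocyte (57.1%), mural (56.3%) and protocadherin genes (31.6%) turned too. Without 1 replicate, hindbrain and cerebellum genes ranged from 61.1 to 88.9%, and endothelial and mural genes each from 62.5 to 68.8%. With CpG ratios of at least 0.48, endothelial (6 genes), oligodendrocyte (5), epidermis (4), muscle (3) and microglia, erythroid, liver and vomeronasal genes (1 each) were at 100%, too few to show a direction. In the same setting hindbrain and cerebellum genes were at 80%, ventral forebrain at 93.3%, sex-linked at 87.5%, ribosomal at 97.4%, proteasome at 97.0%, histone at 90.8% and protocadherin at 85.7%. With shared peaks left out, endothelial genes were at 62.5%, epidermis at 55.6% and histone at 38.8%.

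For broad domains with a gap of 0 bp, ventral forebrain and oligodendrocyte genes were at 0%, pluripotency at 12.5%, housekeeping at 10% and sex-linked at 14.3%. With 3000 bp, mural genes were at 9.09%, housekeeping at 20%, dopamine and serotonin receptors at 0% and ribosomal genes at 16.5% (BH-adjusted Fisher p = 0.0061). From 4 kb, pluripotency was at 12.5%, housekeeping at 25%, receptors at 7.14% and sex-linked at 14.3%. Without 1 replicate, housekeeping ranged from 5 to 25% (BH-adjusted Fisher p = 0.0125 without replicate 1), ribosomal from 3.80 to 6.33%, mural from 0 to 10% and sex-linked from 0 to 14.3%. Without patterning factors, ventral forebrain and muscle genes were at 0%.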

Other observations

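The tests of genes of other regions, of patterning factors, of RefSeq starts, of Hox groups and of transfer RNA genes were chosen only after the results were seen, as was the number of 100 strongest distal peaks.

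Several long noncoding genes of imprinted and X-linked regions carried the mark. Meg3, a maternally expressed imprinted RNA, had a signal of 31.9 with a domain of 4540 bp, Kcnq1ot1 a signal of 23.2 with 4016 bp, and H19 a signal of 4.14 with 336 bp. Xist, the RNA of X inactivation, had a signal of 22.8 and its antisense gene Tsix 13.2, in pools of both sexes. Among gene types, 35.7% of 2959 antisense genes and 15.3% of 5854 lincRNA genes had a replicated peak within 1 kb of a TSS, compared with 2.09% of 9940 processed pseudogenes. Of 403 transfer RNA genes 239 (59.3%, exact 95% interval 54.3 to 64.1%) lay within 1 kb of a replicated peak. The mean was 3.16% for random positions put in place of the genes (one-sided permutation p = 0.001, the smallest that 1000 placements can give). These genes are clustered and not independent, while the random positions were drawn independently, so the random spread is too narrow. Of 279 transfer RNA genes over 2 kb from every GENCODE TSS 155 (55.6%) were near a peak.

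Broad domains covered 38 of the 64 marked genes of the 4 midbrain lists (59.4%), such as Gata3, Otx2 and Lhx9. The tables argue against CpG number within 5 kb of the 5'-most TSS as the whole cause. The highest of 10000 draws of marked genes matched on that number reached 39.1%. The mean draw, at 20.8%, was above the 5.64% of all marked genes, so CpG number goes with part of the excess. Domains that reach beyond that window, as at Gata3, or lie away from that TSS, as at Nr4a2, were not matched along their length. CpG content of the domains themselves therefore stays open. The tables also argue against the joining of replicated peaks over gaps as the whole cause. With a gap of 0 bp, where broad meant 4413 bp or more, the share was 43.8% (28 of 64) against 5.67% of other marked genes, although joining goes with part of it. Joining within the authors' pooled calls was not tested. At Gata3 the pooled peak from 9869636 to 9888334 covered several peaks of each replicate. Genes of other regions in no midbrain list, which include some that are not regulators, were broad in 9 of 48 cases (18.8%, Fisher's exact p = 1.73e-05 against the midbrain lists). Without Hox genes the count was 9 of 39 (23.1%, Fisher's exact p = 0.000465). Among patterning factors alone, 7 of 18 genes of other regions were broad (38.9%), against 21 of 28 in a midbrain list (75.0%, Fisher's exact p = 0.0288). This argues against genes listed only for other regions carrying such domains as often. Part of the pattern goes with regulators in general, since patterning factors in no midbrain list were broad in 30 of 78 cases (38.5%). Genes in both kinds of list, such as Barhl1, Emx2, Isl1 and Six3 (broad) and Nkx2-2 (not broad), counted as midbrain only. The comparisons depend on that choice, and no other was tested. Lmx1a, Lmx1b and Phox2a were not matched as patterning factors. No other biological explanation was tested because the samples form 1 group.

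The 100 strongest distal peaks, with signals of at least 36.3, included 49 within 1 kb of a RefSeq start, 20 of them transfer RNA genes, against a mean of 1.88 and a maximum of 8 in 1000 random placements. Among the others were starts of Tln2 (chromosome 9, 67631626 to 67634758, mm10), Dtna and Flrt1, so part of these peaks may lie at TSSs missing from the annotation used. Among all 4082 distal peaks the share was 11.3%, against a random mean of 1.33%. The median repeat-masked share of the 100 peaks was 11.4%, below the lowest median of the random placements (19.7%). This argues against repeat sequence that collects misplaced reads as the source of the 100 peaks as a set. It cannot decide for a minority of them, or for the 51 with no RefSeq start, which were not measured apart. The 100 peaks had a median CpG ratio of 0.603, near the 0.588 of 2000 sampled TSS peaks and above the highest median of random placements (0.186). For the 51 with no RefSeq start, whose CpG ratio was not measured apart, the source stays open, and no biological explanation was tested.

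Hox genes, which pattern the hindbrain and trunk, were marked in 16 of 39 cases, with a median signal of 5.10 against 44.9 for all marked genes. Tissue of the neighbouring hindbrain could mark the anterior groups, which were marked in 6 of 12 cases for groups 1 to 4, against 6 of 16 for groups 9 to 13 (Fisher's exact p = 0.702), with untested median signals of 7.43 and 3.67 among the marked. On replicate 2's own list the counts were 9 and 6 (Fisher's exact p = 0.0671), and on replicate 1's 5 and 6 (Fisher's exact p = 1). That cause cannot be told apart from marking in the midbrain itself, because the genes are few and the replicates' counts differ. No biological explanation was tested.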
